A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

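Small RNA libraries of hypertrophic scar tissue from the ears of female New Zealand White rabbits were sequenced on an Illumina NovaSeq 6000, per the series' design text. The 6 samples fall into 2 groups of 3, saline and ADSC-Exos. Small RNAs received adaptors at both ends before reverse transcription, per the labels' protocols. The submitters' processing notes name FastQC 1.0.0, Trimmomatic 0.40, STAR 2.7.6a, HTSeq 2.0.3 and DESeq2 1.30.1, with no role or order. The genome build, the miRNA annotation and the use of strand are not given in the sources used here, so no coordinates are printed. How reads shared by paralogous miRNAs such as the let-7 family were assigned is not given in the sources used here. Of the values of such families, 0 of 593 lay off the steps of 1 read, but reads counted in several rows would lie on them too, and the separate values are uncertain to that extent. Of the RefSeq genes of assembly mOryCun1.1, only the neighbours of the miR-194 gene were used.

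The authors deposited a table of 467 mature miRNAs with CPM values, given to 1 decimal apart from a single value with 2 decimals, and each library sums to between 999998 and 1000007 CPM. Scaling by total reads makes each miRNA relative to all others in its library, so a change in an abundant miRNA moves the rest. The whole read total of each library was sought as the number for which its values are multiples of 1 read within 0.05 CPM, taking the lowest value above 0 as 1 read. In ADSC-Exos 3 the best total was tied with another. Simulated libraries gave back the true total in 6 of 6, sometimes as the lowest of several tied totals. A read was worth 0.196 to 0.442 CPM, and 3 reads, the limit that a count of 0 allows, 0.588 to 1.33 CPM. Such limits cover counting error only. Of fits to the recovered reads, limma-voom alone was run.

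The design fixed before the data were examined named a count test for counts and, for normalized values, limma-trend on log2(CPM + 1) for miRNAs with a mean of at least 10 CPM. The latter was used, with Benjamini-Hochberg adjustment over all 224 miRNAs tested, two-sided, and group as the only term. Fold changes on this scale understate the change of low miRNAs. Errors are given as the SD of CPM over 3 libraries or the SE of the log2 fold change. Single miRNAs of interest were also compared by an exact permutation test of the 20 arrangements of log2(CPM + 1), which cannot give a p under 0.1. The 18 miRNA lists were fixed before the data were examined, and the 14 with at least 3 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry as alternatives, all adjusted over the lists. camera asks whether a list moves relative to the other miRNAs, and fry whether its members move on balance in a single direction. miR-486-5p belongs to 4 lists. A row joined a list when its name without copy number and arm was listed. Both arms of a hairpin thus count as separate members, which are not independent, and a reported role may be that of a single arm.

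miRNAs were named by a rule fixed before the data were examined. It takes up to 12 per direction that passed with no overlap between groups, otherwise up to 6 per direction with an unadjusted p under 0.05 and no overlap, all miR-194 rows, the 10 most abundant miRNAs and the 2 most abundant members of each list. It gave miR-206-3p, miR-451-5p, miR-144-5p and miR-181c-3p at lower levels and none at higher levels. miR-29b-3p, miR-29c-3p, miR-29b-2-5p, miR-363-3p, miR-133a-3p, miR-125b-3p, miR-150-5p, miR-744-5p, miR-215-5p, miR-215-3p, miR-653-3p and miR-217-5p were named after their values were seen.

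The alternatives were median-of-ratios scaling, pseudocounts of 0.1 and 10, no level filter, a mean of at least 100 reads, the replicate number as a block, each library left out, limma-voom on the reads from the low-value steps, an estimated correlation and fry. In each leave-out the level filter was applied anew to the remaining libraries. Chosen after seeing the data were quantile scaling, miR-194-3p in saline 2 set to the reads completing its library total, the lists without miR-206-3p or without miR-486-5p, and an estimated correlation together with no filter, a mean of at least 100 reads, without miR-486-5p or each library left out. Planned count fits other than limma-voom were not run. Counting identical rows once was not run, as the 27 duplicated rows are all under the level filter and were not tested in the main comparison. The settings with no filter did test these rows. The fit was tested on 20 simulated sets with 40 changed miRNAs, where 4.32% of calls were false. The list test found the raised list in 20 of 20 sets and called 1 of 260 other lists. The simulated miRNAs varied independently of each other, whereas list members here had estimated correlations of up to 0.92 (cartilage). The false calls of the list test in these data are therefore not known from the simulation. The direction of a list in the comparison of settings is the sign of its median, chosen after camera's own direction had been seen to differ from it for the pro-fibrotic and keratinocyte lists. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.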

Results

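MicroRNAs were profiled in hypertrophic scars of the rabbit ear 21 days after wounding, in a model that uses full-thickness wounds on the inner ear surface of female New Zealand White rabbits. Wounds received saline or ADSC-Exos, the exosomes (small secreted vesicles) of adipose-derived stem cells, at 100 µg in 2 ml. The series' design text places the applications in the first 3 days after injury, whereas the sample labels speak of treatment for 21 days. Small RNA libraries were sequenced for 3 saline and 3 ADSC-Exos samples, and the design text assigns 3 rabbits to each group without stating that each library is a separate rabbit. If libraries shared an animal, the p-values measure only the spread between these samples. The deposited table gives 467 mature miRNAs in CPM, the reads of a miRNA scaled to a common library total. The step between its low values places the miRNA reads per library at 3246695, 2873899 and 3911924 in saline and at 2260645, 3704797 and 5102405 in ADSC-Exos.

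The 10 most abundant miRNAs took 67.7% to 74.5% of each library. They were miR-199a-3p, let-7i-5p, let-7f-5p, let-7a-5p, miR-125b-5p, miR-27b-3p, miR-16b-5p, miR-143-3p, let-7b-5p and miR-21-5p. The let-7 family, which restrains proliferation, held 3 of the 4 highest places, with let-7i-5p at 111889 ± 4455 CPM in saline and 108732 ± 24188 CPM in ADSC-Exos (SD, n = 3 each). miR-199a-3p, a fibroblast-rich miRNA, stood at 112567 ± 9041 CPM in saline and 113591 ± 30024 CPM in ADSC-Exos (SD, n = 3 each). miR-21-5p, which is induced in many fibrotic tissues, averaged 19250.2 ± 3377 CPM in saline and 30466 ± 14665 CPM in ADSC-Exos (SD, n = 3 each), and its log2 fold change of 0.56 ± 0.36 (SE) had an adjusted p of 0.996 in limma. Without ADSC-Exos 1 this fold change was 0.91 and without ADSC-Exos 3 it was 0.20. None of the 10 passed the test. let-7a-5p and miR-199a-3p had log2 fold changes of -0.0080 and -0.015, which turned sign under median-of-ratios and quantile scaling.

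The main comparison asks how the miRNAs of the scar differ after exosome treatment. No miRNA passed the test, and the list with the lowest median was that of red blood cells, whose 5 tested members were all lower in ADSC-Exos scars, with a median log2 fold change of -1.39. The skeletal muscle group was also lower, with a median of -1.04 over 4 tested members and of -0.33 over all 9 measured when no level filter was used, with the muscle-specific miR-206-3p lowest, at 4.6 CPM in saline 3 too. No member of either list passed over all miRNAs tested, and neither list passed with an estimated correlation (adjusted p = 0.117 for both in limma) or in fry (adjusted p = 0.240 for both). The muscle list did not pass without miR-206-3p (adjusted p = 0.0773) or without ADSC-Exos 1 (adjusted p = 0.179), both camera in limma. miR-194-3p, an arm of the miRNA named in the series title, averaged 66.8 ± 55.0 CPM in ADSC-Exos and 2.69 ± 1.75 CPM in saline (SD, n = 3 each), with high values in 2 of the 3 ADSC-Exos libraries. Groups that stand for fibrosis, stem cell exosomes, epithelium, cartilage and leukocytes did not pass the test.

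Of 224 miRNAs with a mean of at least 10 CPM, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.804. At an unadjusted p under 0.05 there were 8, against 11.2 expected by chance, and limma-voom on the reads given by the low-value steps also found 0 at the adjusted and 8 at the unadjusted threshold. The 8 were miR-194-3p and miR-29b-3p at higher levels, and miR-206-3p, miR-451-5p, miR-144-5p, miR-144-3p, miR-486-5p and miR-181c-3p at lower levels. Groups did not overlap for 11 miRNAs (4.91%), where chance gives 10%. The median 95% interval reached 0.88 log2 units to either side. In simulated libraries of the same design, with 40 miRNAs changed in each set, the test called 20.4% of 2-fold, 71.5% of 4-fold and 85.4% of 8-fold changes. Fewer changes would make the adjusted threshold harder to pass, so these shares do not tell how many changes were missed here. The count of 0 became 4 without ADSC-Exos 1 (miR-194-3p, miR-451-5p, miR-486-5p and miR-144-3p) and 1 without saline 3 (miR-206-3p).

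miR-194-3p was at 4.6, 1.16 and 2.3 CPM in the saline libraries and at 3.5, 93.7 and 103.1 CPM in ADSC-Exos 1, 2 and 3. At the library totals above these values stand for 15 and 9 reads in saline 1 and 3 and for 8, 347 and 526 reads in ADSC-Exos, whereas that of saline 2 comes to 3.33 and is not a whole number of reads. Its log2 fold change was 3.37 ± 1.09 (SE), with a 95% interval of 0.91 to 5.83 and an adjusted p of 0.861 in limma. An exact two-sided permutation test of 3 against 3 gave p = 0.2, where the smallest possible is 0.1. Without ADSC-Exos 1, whose value lay inside the saline range, the log2 fold change was 4.86 and the adjusted p in limma 0.000306. The range of adjusted p over all alternatives was 0.000306 to 0.998.

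The other arm, miR-194-5p, was at 24.6, 19.1 and 25.3 CPM in saline and at 20.8, 47.8 and 44.9 CPM in ADSC-Exos. Its log2 fold change was 0.62 ± 0.41 (SE), with an adjusted p of 0.996 in limma and an exact permutation p of 0.3. The ratio of miR-194-3p to miR-194-5p ran from 0.0607 to 0.187 in saline and was 0.168, 1.96 and 2.30 in ADSC-Exos 1, 2 and 3. Among 57 hairpins with both arms tested, miR-194 had the widest gap between the log2 fold changes of its arms, 2.76, followed by let-7b at 1.00. miR-215, whose gene is the neighbour of miR-194 in the RefSeq annotation of assembly mOryCun1.1, was under the level filter. Cartilage miRNAs, too, were lower in ADSC-Exos 1 (mean log2 level of -1.07 relative to the saline mean) than in ADSC-Exos 2 and 3 (0.89 and 0.82). miR-215-5p stood at 3.1, 3.4 and 3.6 CPM in saline and at 1.2, 8.0 and 3.1 CPM in ADSC-Exos.

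Almost all values in the table were whole multiples of the worth of 1 read, within 0.05 CPM, namely 2378 of 2382 values above 0. The 4 others were miR-194-3p in saline 2, at 1.16 CPM, and miR-215-5p in saline 2, ADSC-Exos 1 and ADSC-Exos 2. This takes the lowest value in each library as 1 read. Under finer steps, with totals of 7126099 for saline 2, 6781935 for ADSC-Exos 1 and 7409594 for ADSC-Exos 2, all values would be whole multiples within 0.05 CPM. This tolerance would then take in 71.3%, 67.8% and 74.1% of arbitrary values. It is also wider than the rounding error of 1.16 CPM, given to 2 decimals, so the finer steps do not show that value to be whole reads.

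**Figure D1:**
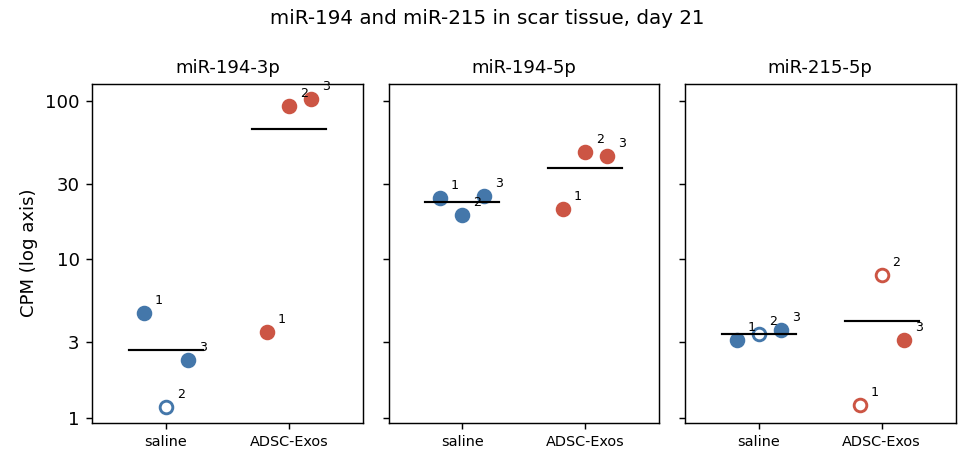
CPM on a log axis of miR-194-3p, miR-194-5p and miR-215-5p in each library of saline (blue) and ADSC-Exos (red), with library numbers beside the points and the mean of 3 as a line. miR-194-3p is at 93.7 and 103.1 CPM in ADSC-Exos 2 and 3 and at 3.5 CPM in ADSC-Exos 1, and open circles mark the 4 values that are not whole multiples of 1 read.

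In the erythroid group, miR-451-5p, which is processed in maturing red cells, averaged 210.2 ± 42.6 CPM in saline and 75.2 ± 57.3 CPM in ADSC-Exos (SD, n = 3 each), a log2 fold change of -1.71 ± 0.50 (SE). miR-144-3p and miR-144-5p, transcribed with miR-451, had log2 fold changes of -1.59 ± 0.64 and -1.39 ± 0.48 (SE). miR-486-5p had -1.39 ± 0.51 (SE), and miR-363-3p, a member of a miR-17-92 paralogue, had -0.68 ± 0.36 (SE). No member passed over all miRNAs tested, and 4 of 5 passed adjusted over the list alone. The list passed camera with a preset correlation of 0.01 (adjusted p = 7.60e-08, limma). It did not pass with an estimated correlation (adjusted p = 0.117) or in fry (adjusted p = 0.240), both in limma. ADSC-Exos 1 stood nearest to saline, with miR-451-5p at 140.7 CPM against 50.7 and 34.3 CPM in ADSC-Exos 2 and 3. The same library stood apart in cartilage miRNAs, whose mean log2 level relative to the saline mean was -1.07 in ADSC-Exos 1, 0.89 and 0.82 in ADSC-Exos 2 and 3, and -0.50, 0.16 and 0.34 in saline.

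In the skeletal muscle group, miR-206-3p was at 131.5 and 145.8 CPM in saline 1 and 2, at 4.6 CPM in saline 3 and at 1.8, 1.6 and 1.2 CPM in ADSC-Exos. Its log2 fold change was -4.24 ± 1.10 (SE) with an adjusted p of 0.804 in limma, and without saline 3 it was -5.79 with an adjusted p of 0.000445. Across all alternatives its adjusted p ranged up to 0.998. miR-1-3p, the most abundant muscle miRNA here, averaged 1668 ± 411 CPM in saline and 1498 ± 870.0 CPM in ADSC-Exos (SD, n = 3 each), and miR-133a-3p had a log2 fold change of -0.70 ± 0.65 (SE). Without ADSC-Exos 1 the log2 fold changes of miR-1-3p and miR-133a-3p were 0.22 and 0.080. The remaining member, miR-486-5p, is shared with the erythroid list. All 4 were lower and 2 passed adjusted over the list alone. The list median was -0.70 without miR-206-3p and also without miR-486-5p. The list passed camera at the preset correlation (adjusted p = 0.000881, limma). It did not pass with an estimated correlation (adjusted p = 0.117) or in fry (adjusted p = 0.240). Nor did it pass without miR-206-3p (adjusted p = 0.0773) or without ADSC-Exos 1 (adjusted p = 0.179), both camera. The estimated correlation of this list was -0.197, below the preset one. Correlation among its members therefore does not account for the rise in unadjusted p from 0.000126 to 0.0167 (camera, limma). The cause of this rise was not tested.

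**Figure D2:**
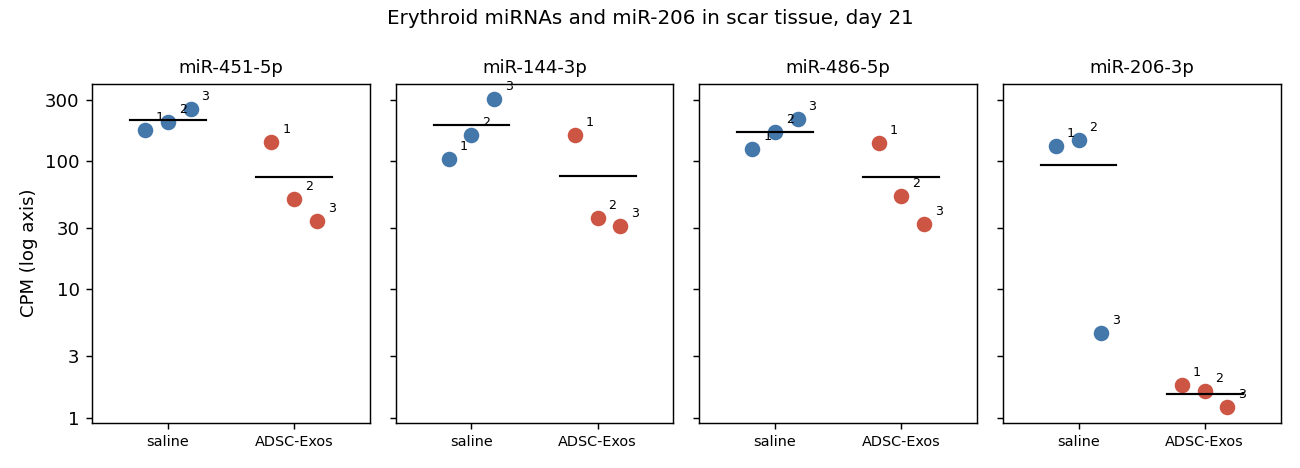
CPM on a log axis of the erythroid miRNAs miR-451-5p, miR-144-3p and miR-486-5p and of the muscle miRNA miR-206-3p in each library, with library numbers beside the points and the mean of 3 as a line. ADSC-Exos 2 and 3 are below all saline libraries for the first 3 miRNAs, and saline 3 is at 4.6 CPM for miR-206-3p.

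Fibrosis-related miRNAs showed no shift that passed. Of 22 tested miRNAs with reported pro-fibrotic roles, 9 were higher and 13 lower, with a median log2 fold change of -0.06 and an upward but uncalled camera result (adjusted p = 0.629, limma). This median turned sign under median-of-ratios and quantile scaling. Of 34 with reported anti-fibrotic roles, 22 were higher and 12 lower (median 0.08, adjusted p = 0.120 in camera, limma). Its miR-29 members of the 3p arm, of a family that represses collagen transcripts, had log2 fold changes of 0.55 ± 0.33 for miR-29a-3p, 0.82 ± 0.34 for miR-29b-3p and 0.25 ± 0.34 for miR-29c-3p (SE). miR-29b-2-5p, the other arm of a miR-29b hairpin and in the list by name only, had 0.30 ± 0.40 (SE). All 4 had an adjusted p of 0.996 in limma. The log2 fold change of miR-29c-3p turned to -0.18 under quantile scaling and to -0.032 without ADSC-Exos 2. The anti-fibrotic list passed without ADSC-Exos 3 (adjusted p = 0.0389), without miR-486-5p (adjusted p = 0.0342) and among miRNAs with at least 100 reads (adjusted p = 0.0436), all camera in limma. With an estimated correlation it did not pass there (adjusted p = 0.293, 0.768 and 0.585) or over all libraries (adjusted p = 0.893), nor in fry (adjusted p = 0.864), and without ADSC-Exos 2 its median was -0.022 (adjusted p = 0.551 in camera, limma). Among 36 miRNAs known from mesenchymal stem cells and their exosomes, 11 were higher and 25 lower (median -0.13, -0.15 to -0.044 over leave-outs and 0.0033 under quantile scaling, adjusted p = 0.490 in camera, limma). miR-181c-3p, a member of that list, was at 24.4 ± 4.50 CPM in saline and 10.03 ± 6.66 CPM in ADSC-Exos (SD, n = 3 each), with a log2 fold change of -1.35 ± 0.48 (SE) and an adjusted p of 0.861 in limma.

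No list of markers of other skin and ear cell types passed, and the medians of several turned sign when a single library was left out. Of 11 keratinocyte and epithelium miRNAs, 5 were higher and 6 lower, with a median of -0.04 that turned sign under both other scalings while the mean was 0.02 and camera pointed up (adjusted p = 0.433, limma). Its epithelial member miR-141-3p averaged 4082 ± 67.5 CPM in saline and 5859 ± 874 CPM in ADSC-Exos (SD, n = 3 each), without overlap and with an adjusted p of 0.996 in limma, and miR-205-5p had a log2 fold change of -0.51 ± 0.50 (SE). This list, then of 10 tested members, passed without ADSC-Exos 3 (median 0.28, adjusted p = 0.0155 in camera, limma), but not with an estimated correlation there (adjusted p = 0.681). Without ADSC-Exos 1 its median was -0.39 (adjusted p = 0.644 in camera, limma). All 4 cartilage miRNAs, both arms of miR-140 and of miR-455, were higher, with a list median of 0.25 and an adjusted p of 0.433 in camera from limma. Among them, miR-140-3p, needed in chondrocytes, was at 0.23 ± 0.62 and miR-140-5p at 0.26 ± 0.61 (SE). Without ADSC-Exos 1, where miR-140-3p was at 836 CPM, the cartilage median was 0.92 (adjusted p = 0.00153 in camera, and 0.670 with an estimated correlation, limma), and without saline 1, ADSC-Exos 2 or ADSC-Exos 3 it was -0.06, -0.17 and -0.06. All 4 smooth muscle miRNAs, both arms of miR-143 and of miR-145, were lower (median -0.27, adjusted p = 0.444 in camera, limma), with miR-143-3p at -0.43 ± 0.53 and miR-145-5p at -0.11 ± 0.38 (SE). This list passed without ADSC-Exos 3 (median -0.34, adjusted p = 0.0434 in camera, and 0.681 with an estimated correlation, limma), and without ADSC-Exos 1 its median was 0.15.

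Of 9 leukocyte miRNAs, 3 were higher and 6 lower (median -0.26, adjusted p = 0.433 in camera, limma), with miR-146a-5p at -0.26 ± 0.38 and miR-155-5p at 0.21 ± 0.41 (SE). Leaving out a library moved this median to between -0.59 (without saline 1, adjusted p = 0.170 in camera, limma) and -0.099 (without saline 2). Of 6 neuronal miRNAs, 1 was higher and 5 lower (median -0.39, adjusted p = 0.433), with miR-218-5p at -0.40 ± 0.39 and miR-7a-5p at 0.07 ± 0.32 (SE), and without a level filter this list, then of 18 members, passed (adjusted p = 0.0419, camera in limma), but not with an estimated correlation (adjusted p = 0.596). Without ADSC-Exos 3 its median was 0.088. The let-7 family had 4 higher and 9 lower of 13 (median -0.07, adjusted p = 0.978). The miR-17-92 cluster and its paralogues had 2 higher and 10 lower of 12 (median -0.14, adjusted p = 0.444), with miR-93-5p at -0.09 ± 0.41 and miR-25-3p at -0.09 ± 0.33 (SE). The imprinted DLK1-DIO3 locus had 6 higher and 10 lower of 16 (median -0.06, turning sign under both other scalings, adjusted p = 0.909), with miR-379-5p at 0.03 ± 0.29 and miR-127-3p at -0.14 ± 0.30 (SE). The 4 HOX cluster miRNAs, both arms of miR-10a and of miR-10b, were lower (median -0.08, turning sign under quantile scaling, adjusted p = 0.901), with miR-10b-5p at -0.22 ± 0.31 and miR-10a-5p at -0.13 ± 0.36 (SE). The liver miRNA miR-122-5p ranged from 2.8 to 38.1 CPM. The endothelial and hypoxia lists, miR-126 and miR-210, were not analysed here.

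**Figure D3:**
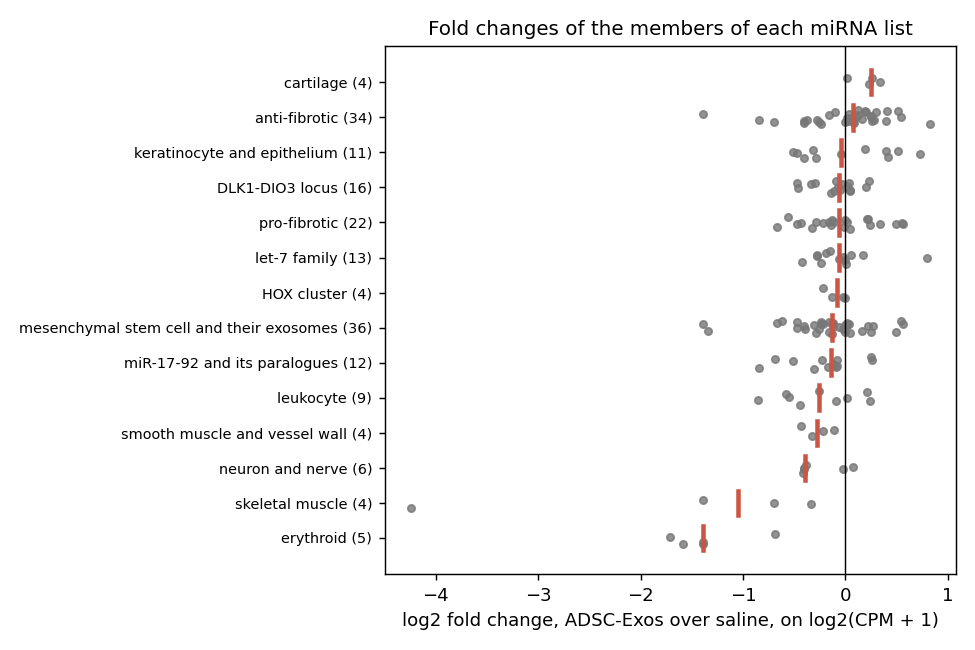
Log2 fold changes of ADSC-Exos over saline, on log2(CPM + 1), of the tested members of each list (grey points, number of members in brackets) with the list median as a red bar. The erythroid and skeletal muscle medians, -1.39 and -1.04, lie lowest. The medians of the pro-fibrotic, keratinocyte and DLK1-DIO3 lists turn sign under both other scalings, and those of the stem cell and HOX lists under quantile scaling.

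The libraries did not separate by group throughout. The first principal component held 45.5% of the variance and the second 28.3%, and on the first ADSC-Exos 1, at -6.26, lay beside the saline libraries at -2.03 to -3.67, while ADSC-Exos 2 and 3 lay at 5.15 and 9.78. Spearman correlations across miRNAs, which are not independent replicates, were 0.935 to 0.975 within saline, 0.916 to 0.966 within ADSC-Exos and 0.934 to 0.970 between groups.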

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

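Of 243 miRNAs under the level filter of the main comparison, 2 were at 0 in all saline libraries and above 3 reads in an ADSC-Exos library. miR-215-3p reached 3.7 CPM, or 19 reads, in ADSC-Exos 3 and 1.1 CPM in ADSC-Exos 2, and was listed at 0 in ADSC-Exos 1. miR-653-3p reached 0.8 CPM, or 4 reads, in ADSC-Exos 3. In the other direction, miR-217-5p had 4 reads in saline 1 and was at 0 in all ADSC-Exos libraries.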

How the results depend on the processing

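Quantile scaling, miR-194-3p in saline 2 at its completing reads, the lists without miR-206-3p or without miR-486-5p, and an estimated correlation together with no filter, at least 100 reads, without miR-486-5p or a library left out were chosen after seeing the data, and the other settings were planned. The planned count fits other than limma-voom were not run, as the values are CPM, nor was counting identical rows once, as none of them passed the level filter of the main comparison. The settings with no filter did test identical rows, so the counts given for them include such rows. Where no cause is given, the cause was not tested. The count of 0 miRNAs at the adjusted threshold stayed 0 in all settings except without ADSC-Exos 1 (4) and without saline 3 (1), so leave-outs ranged from 0 to 4. The count at an unadjusted p under 0.05 ranged from 2 without ADSC-Exos 3 to 28 without ADSC-Exos 1, and was 16 with no filter, where 467 miRNAs were tested. The 2 lists became 4 with no filter, namely erythroid, skeletal muscle, neuronal and the list of the miR-194 and miR-192 clusters (adjusted p = 0.00321 in camera from limma). The last held both arms of miR-194 and of miR-215 but no row of miR-192, and was too small to test with the filter. The number of lists was 0 with an estimated correlation, alone or together with no filter, at least 100 reads, without miR-486-5p or any library left out. It was 0 with fry, 1 without miR-206-3p, 3 without miR-486-5p and 3 at a mean of at least 100 reads. At the preset correlation, leave-outs gave 2 to 5 lists, with 5 without ADSC-Exos 3. The erythroid list passed in all settings except those with an estimated correlation and fry.

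The log2 fold change of miR-194-3p was 2.60 to 4.86 over leave-outs and that of miR-194-5p 0.41 to 0.99, and both stayed above 0 in all settings. miR-206-3p (-5.79 to -2.57), miR-451-5p (-2.29 to -1.28), miR-144-3p (-2.33 to -1.16), miR-144-5p (-1.81 to -1.05), miR-486-5p (-1.96 to -0.93), miR-181c-3p (-1.81 to -0.82) and miR-29b-3p (0.58 to 1.10) kept their direction in all settings that tested them. So did, with ranges over leave-outs, miR-21-5p (0.20 to 0.91), miR-29a-3p (0.23 to 0.85), miR-16b-5p (-0.57 to -0.070), miR-146a-5p (-0.59 to -0.092), miR-218-5p (-0.77 to -0.049) and the leukocyte median (-0.59 to -0.099). The replicate block gave 0 miRNAs, 2 lists and miR-194-3p at 3.37 (adjusted p = 0.533, limma). The groups are different rabbits per the design text, so the shared numbers do not stand for the same animal. Same-number libraries had residual correlations of -0.114, -0.0176 and -0.127 across miRNAs. These values cannot exclude shared handling of such libraries, as residuals sum to 0 within each group.

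Some values turned sign. Under median-of-ratios scaling these were miR-199a-3p (0.049), let-7a-5p (0.056) and the medians of the pro-fibrotic (0.00074), keratinocyte (0.023) and DLK1-DIO3 (0.0012) lists. Under quantile scaling they were miR-199a-3p (0.0055), let-7a-5p (0.14), miR-125b-3p (0.026), miR-29c-3p (-0.18) and the pro-fibrotic (0.051), stem cell (0.0033), keratinocyte (0.23), DLK1-DIO3 (0.10) and HOX (0.0098) lists. These scalings moved the median of all miRNAs from -0.08 to -0.02 and 0.0033. The level filter was applied anew in each leave-out, so the miRNAs tested and the members of some lists changed too. Over leave-outs the following crossed 0: miR-199a-3p (-0.22 to 0.10), let-7i-5p (-0.19 to 0.13), let-7f-5p (-0.041 to 0.10), let-7a-5p (-0.20 to 0.10), miR-125b-5p (-1.16 to 0.16), miR-27b-3p (-0.041 to 0.39), miR-143-3p (-0.88 to 0.25), let-7b-5p (-0.32 to 0.0070), miR-26a-5p (-0.046 to 0.43), miR-205-5p (-0.85 to 0.053), miR-1-3p (-0.76 to 0.22), miR-145-5p (-0.31 to 0.25), miR-140-3p (-0.31 to 0.98), miR-140-5p (-0.16 to 0.99), miR-155-5p (-0.11 to 0.54), miR-7a-5p (-0.10 to 0.29), miR-93-5p (-0.55 to 0.30), miR-25-3p (-0.36 to 0.24), miR-379-5p (-0.14 to 0.18), miR-127-3p (-0.33 to 0.013), miR-10a-5p (-0.30 to 0.16), miR-133a-3p (-1.10 to 0.080), miR-125b-3p (-0.43 to 0.31) and miR-29c-3p (-0.032 to 0.48). List medians that crossed were pro-fibrotic (-0.15 to 0.079), anti-fibrotic (-0.022 to 0.19), keratinocyte (-0.39 to 0.30), smooth muscle (-0.51 to 0.15), cartilage (-0.17 to 0.92), neuronal (-0.71 to 0.088), let-7 (-0.21 to 0.0070), miR-17-92 (-0.45 to 0.054), DLK1-DIO3 (-0.19 to 0.069) and HOX (-0.25 to 0.085). The correlation leaves medians as they are, so with an estimated correlation they turned sign alike, as in pro-fibrotic (0.019), cartilage (-0.063) and HOX (0.0018) without saline 1, keratinocyte without saline 3 (0.12) and ADSC-Exos 3 (0.28), DLK1-DIO3 without ADSC-Exos 1 (0.043) and cartilage without ADSC-Exos 3 (-0.060). Of the values of single miRNAs under other settings, 618 kept direction and side of the threshold, 44 turned sign and 5 passed where the main value had not. Of those of lists, 304 kept both, 44 turned sign (1 of them, keratinocyte without ADSC-Exos 3, now passing), 6 others passed anew and 24 no longer passed. Depth limits low miRNAs such as miR-206-3p, where ADSC-Exos 1 had 4 reads.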

Other observations

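Single libraries stood apart in several abundant miRNAs. Among 116 miRNAs with a mean of at least 100 CPM, miR-125b-5p was at 13018 CPM in ADSC-Exos 3, 5.15-fold below the median of the 6 libraries, while miR-125b-3p from the other arm was at 21.2 CPM there against 3.1 to 16 CPM elsewhere. In the same library miR-744-5p was at 38.4 CPM (5.10-fold below the median), the lymphocyte miRNA miR-150-5p at 269.9 CPM (3.45-fold) and the epithelial miR-205-5p at 1083 CPM (3.01-fold). In ADSC-Exos 1, the smooth muscle miRNA miR-143-3p was at 13577 CPM (3.23-fold below) and miR-140-3p and miR-140-5p, of cartilage, at 836 and 532.6 CPM (both 3.08-fold).

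The tests on the values of miR-194-3p and miR-215-5p, on the arms of miR-194, on erythroid levels by library depth and on other splits of the libraries were chosen after the results were seen, and the other tests on erythroid and cartilage miRNAs were written before their test values were seen, though the list levels were known.

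In the deposited values, 4 values of miR-194-3p and miR-215-5p are not whole multiples of 1 read, when the lowest value of a library is taken as 1 read. Finer steps would make all values whole within 0.05 CPM, a tolerance too wide for the 1.16 CPM of miR-194-3p in saline 2, given to 2 decimals. Of the values of other miRNAs 0 of 2370 were off, which cannot test rounding, as the tolerance equals the largest rounding error, while splitting reads between related miRNAs is argued against by 0 of 593 values in paralogous families. The reads of all rows exceeded the library total by exactly the reads of miR-215-5p in 4 of 6 libraries, against at most 1 for any other miRNA, and in the same libraries under the finer steps, so this row may have been outside the total used for scaling. In saline 2 the reads without miR-215-5p fell 11 short of the total, which 14 reads of miR-194-3p (4.9 CPM in place of 1.16) would complete, and with that value the log2 fold change of miR-194-3p was 2.89 in place of 3.37. Why these 2 miRNAs differ from the rest was not tested, and no biological explanation was tested.

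miR-194-3p was high against miR-194-5p in ADSC-Exos 2 and 3. Values raised after scaling are argued against by the read sums without miR-215-5p, which exceeded the total by 0 at most in these libraries. More of the whole hairpin as the only change would leave the log2 ratio of the arms fixed, if both arms came from a single hairpin. That condition was not tested, and the pattern was itself picked for this ratio. On that condition it is argued against: the ratio departed from its median by 3.191 in ADSC-Exos 2 and 3.416 in ADSC-Exos 3, against a saline SD of 0.539. Of 56 other hairpins none departed by more than 1.502 in 2 libraries, though miR-125b reached 3.779 in a single library. The exosome treatment stays open as an untested biological explanation, and the saline-like value of 3.5 CPM in ADSC-Exos 1 was not explained.

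Erythroid miRNAs were low in ADSC-Exos 2 and 3. Library depth is argued against for ADSC-Exos 2, whose 3704797 reads lay within the saline range: its list level was -2.01 log2 units from that of saline 3, nearest in depth, against a saline SD of 0.336. For ADSC-Exos 3, deeper than all other libraries and at -2.36 from saline 3, it stays open: the line through the 3 saline libraries predicts -0.383 times its level, the other direction, but beyond their depth, and thinning to 2260645 reads (mean log2 fold change of -1.353 before, -1.36 after) leaves CPM as they are on average (median shift of 0.0264) and decides nothing. Less blood in the tissue sampled may account for the low erythroid levels. The log2 ratios of miR-451-5p, miR-144-3p and miR-486-5p varied less than their levels, with an SD of 0.364 against 1.157, or 0.314 times. The SD of levels takes in the fall in ADSC-Exos 2 and 3, so 0.314 does not show a fixed ratio. Values as low came up in 0.01% of 10000 random sets, and the value over all 5 members was 0.411. The sets were drawn from all tested miRNAs, whereas miR-144 is transcribed with miR-451 and the members were known to be low together. That share therefore decides nothing about the cause. Other lists differed too, in either direction, with leukocyte levels of 0.11, -0.26 and -0.62 and cartilage levels of -1.07, 0.89 and 0.82 in ADSC-Exos 1, 2 and 3. A shared change of the erythroid miRNAs in the scar with treatment would give a low value too and was not tested.

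A hypothesis on cartilage is that the tissue sampled held different shares of it. The log2 ratio of miR-140-3p to miR-455-3p varied by 0.525 times the SD of their levels, as low as in 1.63% of 10000 random pairs. This was just above the bound of 0.5 set for this explanation. Regulation of both miRNAs together would keep a fixed ratio too, so even a value under the bound would not tell it apart from tissue shares.

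The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 miRNAs at the adjusted threshold and the highest other split 0, so 10 of 10 gave as many. For lists the real split gave 2 and the highest other split 6, with 6 of 10 splits giving 2 or more. The smallest adjusted p of any list was 7.60e-08 in the real split and at least 2.77e-06 in the others (camera at the preset correlation, limma). Being the lowest of 10 splits cannot give a share under 0.05 either. The split of saline 1, saline 2 and ADSC-Exos 1 against the rest had 37 miRNAs at an unadjusted p under 0.05 against 8 in the real split, of which 0 passed in limma after adjustment, and 6 lists. The other split with 6 lists, saline 1, ADSC-Exos 1 and ADSC-Exos 2 against the rest, had 3 such miRNAs.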
